A study of Rattus norvegicus with 52 samples.

How the data were processed

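Total RNA from liver sections of F344 rats was hybridized to one-colour oligonucleotide arrays, with 1 array per sample and 52 arrays. The rats had received clofibric acid (CA) at 0, 0.29 or 0.54%, as the labels give the dose. The route and length of treatment are not given in the sources used here. The deposited table holds 1 linear intensity per probe set and array, in whole numbers, for 8799 probe sets of which 59 are controls. The authors' software, scaling target and presence calls are not stated. Between 20.6% and 30.1% of the intensities of an array lay below 0, as a difference between matched and mismatched probes gives. The number of arrays and the signal over background limit the precision, since an array has no read depth.

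Groups, the limma comparisons and all but 4 of the alternative settings were chosen before the data were examined. The rule for low values was fixed in the same way. Because 55.5% of all intensities lay under 20, the 10th percentile of the positive intensities, 4, served as the floor, and lower values were raised to it before taking log2. The 2% trimmed means of the arrays ranged from 38.3 to 127 around a median of 109, beyond the 5% that had been set as the limit for keeping the deposited scale, so the log2 values were quantile normalized between all 52 arrays. Log2 intensities and fold changes below are on that normalized scale, and plain intensities are the deposited ones. Control probe sets were kept out of the tests and used for quality measures.

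Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test). A probe set was called when its Benjamini-Hochberg adjusted p lay under 0.05 among the non-control probe sets that were above the floor on at least 1 array of the fit. The 3 entire-section groups were fitted together, as were the 3 stained-section groups. The contrasts of stained with entire sections used those 6 groups. Microdissected samples, with 1 array at each CA dose, were fitted with all 15 groups, the doses averaged and the spread pooled. The lone arrays are thereby assumed to vary like the replicated groups. Dehydrated and LCM-reference-time sections, with 1 array per dose, were described without a test. Correlations of CA effects between preparations were taken across probe sets, which are not independent replicates. Array quality measures were compared by two-sided exact permutation tests (SciPy 1.17.1, Python 3.11.15) with Benjamini-Hochberg adjustment over the family of 35. Plots were drawn with matplotlib 3.10.9.

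The labels do not say that replicates of a group came from separate animals, so the p-values measure the spread between these samples and part of it may be technical. They also do not say whether stained and entire sections came from the same rats, nor which animals gave the microdissected regions. No batch or scan date is given.

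The table gives no gene names, and 0 of the accessions inside the probe set IDs matched the gene table used here. Gene lists, cell type markers, a panel of CA-responsive genes and a rule of naming genes had been fixed by gene symbol and could not be used. List tests with camera and fry, and the 2 alternatives that concern them, were therefore not run. In place of named genes, up to 2 probe sets with the largest rise and 2 with the largest fall are given for each comparison, by their ID. They were taken from the called probe sets that were above the floor on every array compared. This rule, and a score of the CA response, were chosen after the data had been examined. Probe sets named by the rule had the largest called changes on the arrays compared. Where those arrays are said below to lie apart, this largely follows from the choice and is no separate support.

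The alternatives were the deposited scale centred on the median of each array, a floor of 20, a filter at the 25th percentile of all intensities (0), all 15 groups in the fit (for microdissected samples, only the microdissected and entire groups), array quality weights, the replicate number as a block, a variance prior with trend and robust fitting, a 2-fold minimum, and leaving out each replicate. Chosen after seeing the data were quantile normalization before the floor, a filter at the 75th percentile (66), the GAPDH 3'/5' ratio as a covariate, and leaving out the 6 arrays in doubt. Those are 3 entire-section arrays with a GAPDH 3'/5' ratio above 4 and 3 stained arrays with a 5S rRNA intensity above 200. The procedure was tested on simulated data with 200 changed probe sets, all with a mean log2 intensity above 5 in entire controls. It recovered 75% of 2-fold changes for 0.54% CA against control in entire sections, 46% for the same contrast in stained sections, 59% for stained against entire controls, 27% for the difference of the 0.54% CA effect between those preparations, and 15% for CA in microdissected samples. The false share of the calls was 3.37%, 8.09%, 4.52%, 7.55% and 6.10% in the same order, above the 5% aimed at in 3 of the 5 contrasts. Changes in dimmer probe sets were not simulated. The simulated noise had the same spread in every group, so the false share under unequal spreads was not tested.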

Results

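The series measured RNA abundance in liver sections of F344 rats given clofibric acid (CA), a fibrate drug that activates the nuclear receptor PPARα, with arrays of 8740 non-control probe sets. By its title it sets whole liver beside liver taken by laser capture microdissection (LCM), in which chosen regions of a section are isolated under a microscope. Entire sections gave 8 control arrays, 8 at 0.29% CA and 6 at 0.54% CA. Stained sections gave 8 control arrays, 7 at 0.29% and 5 at 0.54%. Dehydrated sections and sections labelled LCM reference time gave 1 array at each dose, and microdissected liver gave 2 control arrays and 1 at each CA dose. The mean intensity of an array lay between 163 and 202 in entire sections and between 132 and 196 in stained sections. The median correlation between control replicates was 0.958 in entire sections (n = 8), 0.906 in stained sections (n = 8) and 0.879 between the 2 microdissected controls.

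Measures used as signs of RNA quality differed between the preparations. The ratio of the 3' to the 5' probe set of GAPDH, which rises when the 5' side of transcripts is lost, had a median of 1.54 in entire sections (22 arrays), 8.45 in stained sections (20 arrays), 11.8 in dehydrated sections (3 arrays), 4.70 in LCM-reference-time sections (3 arrays) and 7.71 in microdissected liver (4 arrays). Among controls its log2 was 3.31 ± 0.78 (SD, n = 8) after staining and 0.80 ± 0.78 (SD, n = 8) in entire sections (exact permutation p = 0.000466, adjusted 0.00544). The same ratio for beta-actin was 2.40 ± 0.52 against 1.10 ± 0.70 (SD, n = 8 each; exact permutation p = 0.00218, adjusted 0.0152). The 3' beta-actin probe set was lower in all 8 stained controls than in every entire control, at a mean log2 intensity of 7.53 against 10.13 (n = 8 each; exact permutation p = 0.000155, the smallest these arrays allow, adjusted 0.00272). It was lower on the deposited scale too, with and without centring. Stained controls had 2005 probe sets above an intensity of 66 and entire controls 2392 (exact permutation p = 0.000155, adjusted 0.00272, n = 8 each). The 50 brightest probe sets took 26.4% of the signal in stained controls and 19.2% in entire controls (exact permutation p = 0.000777, adjusted 0.0068, n = 8 each). Of 28 tests between CA and control arrays of 1 preparation, 1 passed the adjustment: stained sections at 0.54% CA had 2216 probe sets above 66 and their controls 2005 (exact permutation p = 0.00311, adjusted 0.0181, n = 5 and 8).

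**Figure D1:**
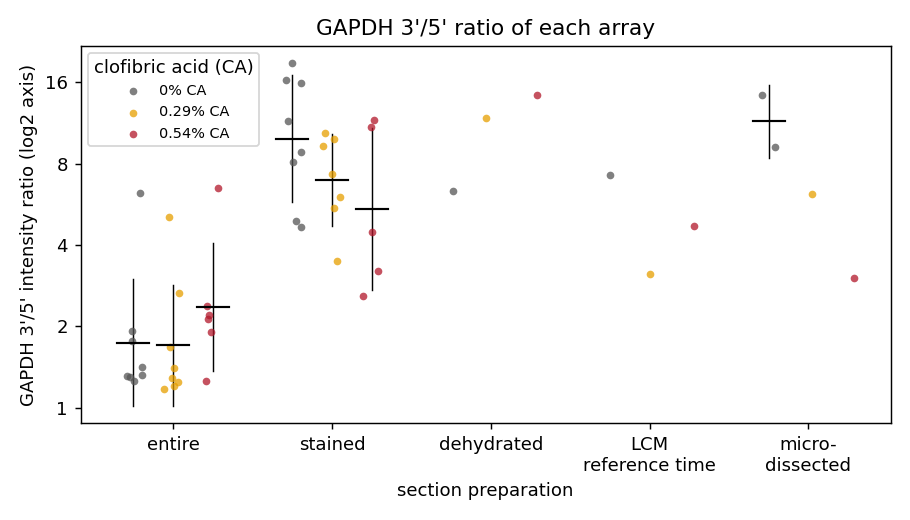
GAPDH 3'/5' intensity ratio of each array (log2 axis) by section preparation and CA dose; points are arrays, horizontal lines are group means and vertical lines span 1 SD on each side, both taken on the log2 scale, where a group has replicates. Entire sections had a median ratio of 1.54 and stained sections one of 8.45.

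CA changed the RNA of entire sections at both doses. At 0.29% CA, 433 probe sets rose and 444 fell against control, of 7804 tested, and at 0.54% CA 632 rose and 604 fell. Probe set j02749_at rose from an intensity of 185 ± 74.7 (SD, n = 8) in controls to 4699 ± 786 (SD, n = 8) at 0.29% and 4670 ± 739 (SD, n = 6) at 0.54%, a 35.1-fold and a 41.7-fold rise after normalization. Probe set m00002_at fell from 1274 ± 249 (SD, n = 8) to 35.9 ± 23.6 (SD, n = 8) and 14.3 ± 7.58 (SD, n = 6), which is 47.2-fold and 107-fold lower. The log2 fold changes of j02749_at were 5.14 ± 0.16 (SE, adjusted p = 1.12e-15) and 5.38 ± 0.17 (SE, adjusted p = 1.56e-15). Those of m00002_at were -5.56 ± 0.37 (SE, adjusted p = 3.27e-10) and -6.74 ± 0.40 (SE, adjusted p = 3.71e-11). Probe set m26594_at rose 15.4-fold at 0.29% (log2 3.94 ± 0.19, SE, adjusted p = 2.49e-12) and 23.9-fold at 0.54% (log2 4.58 ± 0.21, SE, adjusted p = 4.10e-13). At 0.29%, u46118_at was 17.9-fold lower (log2 -4.16 ± 0.26, SE, adjusted p = 1.05e-10), and at 0.54% m93297cds_at was 17.9-fold lower (log2 -4.17 ± 0.21, SE, adjusted p = 3.77e-12). For each of these 5 probe sets, all CA arrays compared lay on 1 side of all 8 controls, as their choice by large called changes makes likely. Changes of at least 2-fold numbered 356 at 0.29% and 558 at 0.54%. With all 15 groups in the fit the counts were 539 and 790, and array weights gave 1933 at 0.54%. The fold of j02749_at at 0.54% was 26.9 on the deposited scale, and that of m00002_at was 54.1 with a floor of 20.

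The 2 doses moved the same probe sets in entire sections. Of the calls, 340 were higher and 351 lower at both doses, where independent calls would share 35.1 and 34.4, and 0 were called in opposite directions. Both doses are compared with the same controls, which alone gave a correlation across probe sets of 0.462 in 100 simulations of unchanged groups. The observed correlation was 0.809, and it was 0.668 when each dose was set against a separate set of 4 controls. Over all 8740 probe sets, which include those at the floor on every array of the fit, the covariance was 0.283 against 0.0385 in the simulations, and the difference of 0.245 is not accounted for by the shared controls. Over the 7804 tested alone it was 0.317.

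The higher dose differed from the lower dose in entire sections at 79 probe sets, of which 37 were higher and 42 lower. Probe set rc_aa875269_at rose from 61.5 ± 23.6 (SD, n = 8) at 0.29% to 306.5 ± 147 (SD, n = 6) at 0.54%, 4.72-fold (log2 2.24 ± 0.24, SE, adjusted p = 9.18e-06). Probe set m15114_g_at rose from 38.0 ± 6.21 (SD, n = 8) to 195 ± 78.1 (SD, n = 6), 4.59-fold (log2 2.20 ± 0.17, SE, adjusted p = 1.55e-07). Probe set j00738_s_at fell 3.62-fold, from 1295 ± 276 (SD, n = 8) to 381 ± 85.2 (SD, n = 6; log2 -1.86 ± 0.18, SE, adjusted p = 3.96e-06). Probe set rc_ai175959_at was 4.0-fold lower (log2 -2.0 ± 0.36, SE, adjusted p = 0.00528), a call lost with all 15 groups in the fit (adjusted p = 0.0509). All 6 arrays at 0.54% lay on 1 side of all 8 at 0.29% for these 4 probe sets. The count was 34 on the deposited scale, where 58.8% were higher against 46.8% here, 331 with array weights, 132 with a floor of 20, 41 with all 15 groups and 32 with a 2-fold minimum. It was 47, 47, 45 and 39 without replicates 1, 2, 3 and 4 at 0.29%, and 33 and 41 without replicates 2 and 5 at 0.54%.

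CA changed the RNA of stained sections in the same direction. At 0.29% CA, 145 probe sets rose and 141 fell against stained controls, of 7913 tested, and at 0.54% CA 247 rose and 252 fell. Probe set j02749_at rose from 171 ± 134 (SD, n = 8) to 5681 ± 1052 (SD, n = 7) at 0.29% and 6945 ± 1101 (SD, n = 5) at 0.54%, 34.6-fold and 44.2-fold. Probe set k03249_at rose 17.7-fold and 33.0-fold, from 131 ± 149 (SD, n = 8) to 1804 ± 1053 (SD, n = 7) and 3199 ± 857 (SD, n = 5). The log2 fold changes of j02749_at were 5.11 ± 0.29 (SE, adjusted p = 3.22e-10) and 5.46 ± 0.32 (SE, adjusted p = 3.77e-10). Those of k03249_at were 4.14 ± 0.58 (SE, adjusted p = 9.84e-05) and 5.04 ± 0.64 (SE, adjusted p = 2.08e-05). At 0.29%, u46118_at was 19.97-fold lower (log2 -4.32 ± 0.30, SE, adjusted p = 8.02e-09) and rc_aa893325_at 12.6-fold lower (log2 -3.65 ± 0.49, SE, adjusted p = 6.50e-05). At 0.54%, m00002_at was 35.1-fold lower (log2 -5.13 ± 0.63, SE, adjusted p = 1.43e-05; 16.2-fold with a floor of 20) and x14552_at 15.7-fold lower (log2 -3.97 ± 0.43, SE, adjusted p = 3.21e-06). For each of these 6 probe sets, all CA arrays compared lay on 1 side of all 8 stained controls. With all 15 groups in the fit, where the spread is pooled with entire sections, the counts were 546 and 964. With the GAPDH ratio as a covariate, 301 probe sets were called at 0.54%, and on the deposited scale the median of all probe sets shifted by -0.14 at that dose. Stained sections shared 125 higher and 117 lower calls between the doses, where independent calls would share 4.53 and 4.49, and 0 were opposite. Their correlation across probe sets was 0.779, against 0.427 in simulations of unchanged groups with the same shared controls and 0.572 with separate controls. Over all 8740 probe sets the covariance was 0.311 against 0.0725 in those simulations, a difference of 0.238, and over the 7913 tested alone it was 0.343.

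Between the doses, 5 probe sets differed in stained sections. Probe set j00738_s_at was 3.68-fold lower at 0.54% than at 0.29% (517 ± 205, SD, n = 5, against 1777 ± 557, SD, n = 7; log2 -1.88 ± 0.22, SE, adjusted p = 0.000469). Probe set m15114_g_at was 4.34-fold higher (149 ± 42.5, SD, n = 5, against 37.1 ± 25.5, SD, n = 7; log2 2.12 ± 0.37, SE, adjusted p = 0.0354), and j02657_s_at 2.32-fold lower (log2 -1.21 ± 0.20, SE, adjusted p = 0.0354). All 5 arrays at 0.54% lay on 1 side of all 7 at 0.29% for these 3 probe sets. The other calls, named after their values were seen, were af065431_s_at at log2 1.36 ± 0.24 (SE, adjusted p = 0.0354) and l02529_at at log2 -2.80 ± 0.51 (SE, adjusted p = 0.0371), both at the floor on some arrays. Leaving out 1 array ended the call of m15114_g_at in 8 of 12 fits and that of j02657_s_at in 9 of 12, with adjusted p up to 0.116 for both without replicate 3 at 0.54%, while in those fits the folds stayed at 3.97 to 4.82 and 2.16 to 2.36. The count was 1 without replicate 1, 2 or 3 at 0.29% or replicate 1 or 3 at 0.54%, 2 without replicate 6 at 0.29% or replicate 2 at 0.54%, 3 without replicate 5 at either dose, and 9 without replicate 4 at either dose. It was 1 on the deposited scale, where j00738_s_at, a lower probe set, passed, and 18 or 19 with all 15 groups or array weights. With the GAPDH ratio as a covariate it was 2, without m15114_g_at (log2 2.09 ± 0.39, SE, adjusted p = 0.0583). Without the 6 arrays in doubt, the calls of m15114_g_at (log2 1.78 ± 0.34, SE, adjusted p = 0.0738) and j02657_s_at (log2 -1.27 ± 0.23, SE, adjusted p = 0.0536) were lost.

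The CA effect had the same direction in stained and entire sections. At 0.29%, 127 probe sets rose and 114 fell in both preparations, where independent calls would share 8.30 and 8.24, and at 0.54% 192 rose and 177 fell in both against 20.6 and 20.1. No probe set was called in opposite directions at either dose. Of the probe sets called in entire sections and tested in both, 92.8% had the same sign in stained sections at 0.29% and 87.0% at 0.54%. The correlation across probe sets was 0.612 at 0.29% and 0.540 at 0.54%, with separate controls for each preparation.

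**Figure D2:**
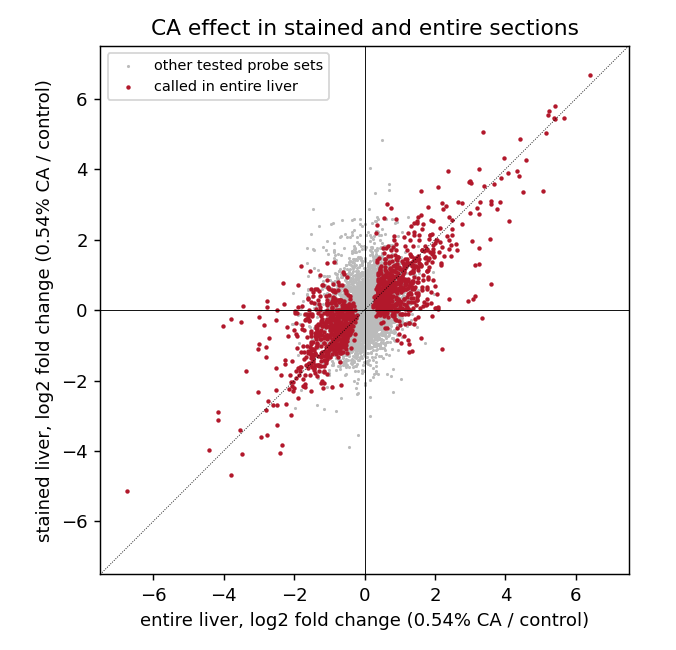
Log2 fold change of 0.54% CA against control in stained sections (vertical axis) and entire sections (horizontal axis), 1 point per probe set, with those called in entire sections in red. The correlation across probe sets was 0.540 and 87.0% of the called probe sets had the same sign.

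Tests of the difference between stained and entire sections in the CA effect called 7 probe sets at 0.29% (2 higher and 5 lower in stained sections) and 11 at 0.54% (2 higher and 9 lower). Probe set rc_aa799326_s_at rose in entire sections from an intensity of -6.75 ± 14.0 (SD, n = 8) to 86.1 ± 47.8 (SD, n = 8) and 256 ± 82.9 (SD, n = 6). Probe set ab005743_g_at rose there from -4.50 ± 5.78 (SD, n = 8) to 55.1 ± 25.2 (SD, n = 8) and 133 ± 46.0 (SD, n = 6). Both were at the floor on all 20 stained arrays and on every dehydrated, LCM-reference-time and microdissected array, so no fold is given after those preparations. Their fitted log2 differences were -3.46 ± 0.52 (SE, adjusted p = 0.000213) and -5.38 for rc_aa799326_s_at, and -3.19 ± 0.45 (SE, adjusted p = 6.67e-05) and -4.59 for ab005743_g_at, at 0.29% and 0.54%. With all stained arrays at the floor, controls included, these values restate the rise in entire sections and measure no CA effect in stained ones. They depend on the floor and were -1.65, -3.28, -1.16 and -2.27 with a floor of 20. Probe set e00001cds_i_at, named after its values were seen, went the other way, with the signal in stained sections: it fell from 73.5 ± 54.4 (SD, n = 8) in stained controls to the floor on most stained CA arrays (log2 -3.46 ± 0.51, SE, adjusted p = 0.000173 at 0.29%, and -3.89 ± 0.56, SE, adjusted p = 9.89e-05 at 0.54%). It was at the floor on 21 of 22 entire arrays, so its differences of -3.01 (adjusted p = 0.0349) and -3.44 (adjusted p = 0.0176) restate the fall in stained sections. None of the 7 or 11 probe sets was above the floor on all arrays, and 6 and 9 of them were at the floor on most stained arrays. At an unadjusted p under 0.05 there were 391 and 801 probe sets. The 0.29% count was 11 without entire control replicate 7, stained control replicate 4 or stained control replicate 8, and 13 without entire replicate 7 at 0.29%. The 0.54% count was 20 without entire control replicate 7 or stained control replicate 4, and 7 without stained replicate 1 at 0.54%. Without the 6 arrays in doubt the counts were 17 and 22, array weights gave 15 and 22, a floor of 20 gave 16 and 30, and on the deposited scale 16.7% of the 0.29% calls were higher against 28.6% here.

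Stained control liver differed broadly from entire control liver. Against entire controls, 1347 probe sets were higher and 1128 lower in stained controls, of 8191 tested, beside the higher GAPDH 3'/5' ratio. Probe set rc_ai014135_at was 11.3-fold higher in stained controls, at 317 ± 261 against 31.8 ± 18.2 (SD, n = 8 each; log2 3.50 ± 0.64, SE, adjusted p = 5.07e-05). Probe set l24776_at was 7.67-fold higher, at 154 ± 89.4 against 30.3 ± 18.1 (SD, n = 8 each; log2 2.94 ± 0.55, SE, adjusted p = 7.26e-05). Probe set rc_ai169735_g_at was 22.2-fold lower, at 26.3 ± 23.0 against 580.3 ± 73.6 (SD, n = 8 each; log2 -4.47 ± 0.59, SE, adjusted p = 2.88e-07). Probe set x15734_at was 21.3-fold lower, at 112 ± 150 against 1326 ± 520 (SD, n = 8 each; log2 -4.41 ± 0.72, SE, adjusted p = 9.39e-06). For the first 3 of these, no stained control overlapped the entire controls, and for x15734_at entire control replicate 7 lay within the range of the stained controls. On the single dehydrated control array, with a GAPDH 3'/5' ratio of 6.36, the intensities were 150.0 for rc_ai014135_at, 124 for l24776_at, 42 for rc_ai169735_g_at and 234 for x15734_at, each on the same side of the mean of the entire controls as in stained controls. Changes of at least 2-fold numbered 594 higher and 850 lower. The split between higher and lower depended on the scaling: 54.4% of the calls were higher here and 74.2% of 3798 on the deposited scale, where the median of all probe sets shifted by 0.42 on the log2 scale against 0.09 here. With the GAPDH ratio as a covariate 400 probe sets were called, among them rc_ai169735_g_at at 8.23-fold lower (log2 -3.04 ± 0.82, SE). The covariate ended the calls of rc_ai014135_at at 7.62-fold (log2 2.93 ± 0.95, SE, adjusted p = 0.0636) and l24776_at at 6.07-fold (log2 2.60 ± 0.82, SE, adjusted p = 0.0567), where the SE rose and the fold fell by less than 1.5 times, and that of x15734_at, where the fold fell to 2.10 (log2 -1.07 ± 0.77, SE, adjusted p = 0.556).

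On single arrays of dehydrated and LCM-reference-time sections, which were not tested, most CA effects had the direction seen in entire sections. The intensity of j02749_at was 218 in the dehydrated control, 5493 at 0.29% and 8003 at 0.54%, and 94, 3665 and 7618 in LCM-reference-time sections. That of rc_aa893325_at was 712, 87 and 83 in dehydrated sections and 211, 16 and 30 in LCM-reference-time sections. Of the probe sets called in entire sections, 78.8% had the same sign in dehydrated sections at 0.29% and 75.4% at 0.54%, and 72.3% and 71.4% in LCM-reference-time sections. A probe set at the floor on both arrays of a pair showed no change and counted as not the same sign. The remaining shares are therefore not all opposite effects. The correlations with the entire-section effect across probe sets were 0.371 and 0.346 in dehydrated sections and 0.198 and 0.236 in LCM-reference-time sections. With 1 array per group such values are lowered by array noise. Pairs of single arrays were therefore set against the effect in 1 part of the entire-section arrays. Median correlations at 0.29% and 0.54% were 0.429 and 0.560 for single entire-section pairs from the other part. They were 0.277 and 0.298 for stained pairs, 0.342 and 0.329 for dehydrated pairs, and 0.185 and 0.226 for LCM-reference-time pairs. The highest LCM-reference-time values, 0.210 and 0.234, lay below the lowest for entire-section pairs, 0.303 and 0.350. Noise of the size on single entire-section arrays thus does not account for all of the loss there.

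A CA score gathered the response of each array: the mean log2 intensity of 153 probe sets that rose at least 2-fold at both doses in entire sections, minus that of 128 that fell. In stained sections, which had no part in choosing the probe sets, it was -1.59 ± 0.19 (SD, n = 8) in controls, 1.22 ± 0.10 (SD, n = 7) at 0.29% and 1.77 ± 0.15 (SD, n = 5) at 0.54%. The difference from control had an exact permutation p = 0.000311 at 0.29% (n = 7) and p = 0.00155 at 0.54% (n = 5), the smallest these arrays allow, with adjusted values of 0.000777 and 0.00155 over 5 tests, of which the 3 that include entire controls are not independent of the choice of probe sets. The third of these set stained controls against entire controls, which scored -2.19 ± 0.24 (SD, n = 8; exact permutation p = 0.000622, adjusted 0.000833). The single arrays scored -1.46, 1.33 and 1.63 in dehydrated sections and -1.44, 1.24 and 1.84 in LCM-reference-time sections, in order of dose. Microdissected controls scored -1.65 and -1.42, and microdissected CA arrays 1.10 at 0.29% and 1.87 at 0.54%. In the 4 preparations other than entire sections, 0 CA arrays scored below the highest control, while in entire sections the choice of probe sets fixed the separation.

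**Figure D3:**
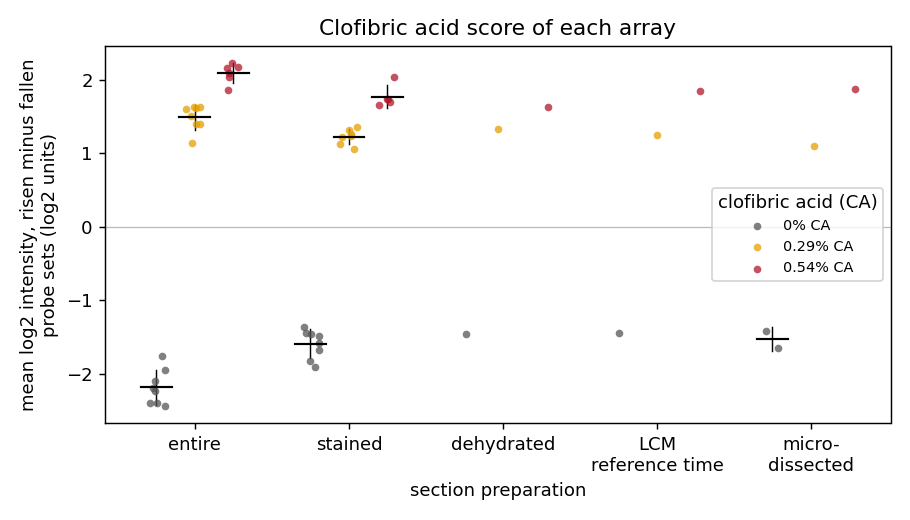
CA score of each array (log2 units) by section preparation and CA dose; points are arrays, horizontal lines are group means and vertical lines span 1 SD on each side where a group has replicates. In stained sections controls averaged -1.59 and CA arrays 1.22 and 1.77, and microdissected CA arrays scored 1.10 and 1.87.

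CA also changed the RNA of microdissected liver. Against the 2 microdissected controls, 480 probe sets were higher and 589 lower on the 2 CA arrays, of 8318 tested. Probe set j02749_at rose 31.1-fold, from 96.5 ± 37.5 (SD, n = 2) to 3490 at 0.29% and 6123 at 0.54% (log2 4.96 ± 0.44, SE, adjusted p = 2.74e-11; 50.6-fold on the deposited scale). Probe set k03249_at rose 24.5-fold, from 56.5 ± 10.6 (SD, n = 2) to 931 and 3358 (log2 4.62 ± 0.82, SE, adjusted p = 9.40e-05). Probe set rc_aa893325_at was 33.9-fold lower, at 12 and 27 against 527 ± 252 (SD, n = 2; log2 -5.08 ± 0.75, SE, adjusted p = 4.14e-06), and u39549_at 19.5-fold lower, at 62 and 12 against 478 ± 158 (SD, n = 2; log2 -4.29 ± 0.62, SE, adjusted p = 2.63e-06). Both CA arrays lay on 1 side of both controls for these 4 probe sets. The spread pooled over all 15 groups had a median SD of 0.595, below the 0.679 of stained sections. The 2 microdissected controls correlated at only 0.879, so their own spread may be larger and the calls too many. The GAPDH 3'/5' ratio was 14.3 and 9.22 on the 2 controls, 6.20 at 0.29% and 3.02 at 0.54%. It therefore moved together with CA in this comparison. The microdissected calls shared 119 higher and 131 lower probe sets with stained sections at 0.54%, where independent calls would share 13.1 and 16.6, and 0 were opposite. With entire sections at 0.54% they shared 144 higher and 151 lower, against 33.9 and 39.3, and 9 were opposite. Of the 1069 calls 362 were above the floor on every array compared, and the count was 698 without microdissected control replicate 2. The count was 312 on the deposited scale, where 56.7% were higher against 44.9% here, 335 with array weights, 509 above the 75th percentile, and 1841 when only microdissected and entire groups gave the spread.

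**Figure D4:**
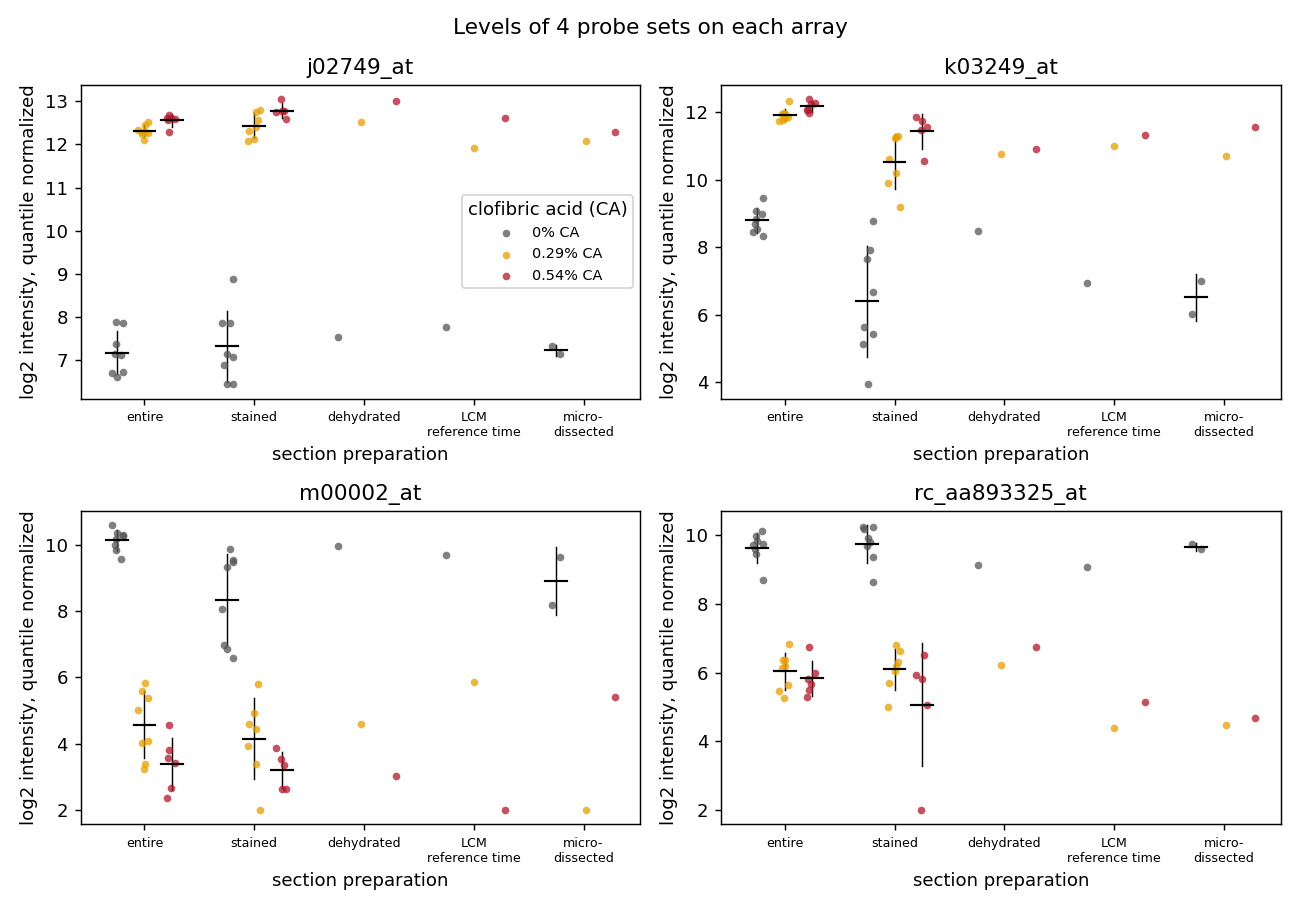
Log2 intensity after normalization of probe sets j02749_at, k03249_at, m00002_at and rc_aa893325_at on each array, by section preparation and CA dose; points are arrays, horizontal lines are group means and vertical lines span 1 SD on each side where a group has replicates. Probe set j02749_at was 35.1-fold higher at 0.29% CA in entire sections and 34.6-fold higher in stained sections.

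Microdissected control liver differed from entire control liver at 1250 higher and 896 lower probe sets. Probe set rc_ai014135_at was 50.3-fold higher, at 810.0 ± 424 (SD, n = 2) against 31.8 ± 18.2 (SD, n = 8; log2 5.65 ± 1.01, SE, adjusted p = 8.46e-05), and l24776_at 27.3-fold higher (log2 4.77 ± 0.89, SE, adjusted p = 0.000125). Probe set x62086mrna_s_at was 78.5-fold lower, at 24.5 ± 2.12 (SD, n = 2) against 2872 ± 313 (SD, n = 8; log2 -6.29 ± 1.30, SE, adjusted p = 0.000405). Probe set s56937_s_at was 52.7-fold lower, at 11.5 ± 0.71 (SD, n = 2) against 959 ± 190 (SD, n = 8; log2 -5.72 ± 1.04, SE, adjusted p = 9.78e-05). The 11.5 lay at the level of the median intensities of the 2 microdissected control arrays, 11 and 12, so the exact fold is uncertain. Both microdissected controls lay beyond all 8 entire controls for these 4 probe sets. The fold of rc_ai014135_at was 88.8 without microdissected control replicate 1 and 28.5 without replicate 2, and that of l24776_at 57.8 and 12.9. The count was 923 without replicate 2, 328 with array weights, which ended the calls of rc_ai014135_at, l24776_at and x62086mrna_s_at (log2 5.91 ± 1.83, 4.71 ± 1.52 and -6.30 ± 1.96, SE), and 897 with the GAPDH ratio as a covariate. That covariate left x62086mrna_s_at 8.14-fold lower (log2 -3.02 ± 1.37, SE, adjusted p = 0.157) and s56937_s_at 11.8-fold lower (adjusted p = 0.0425), and on the deposited scale the median of all probe sets shifted by 0.29.

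The CA effect differed between microdissected and entire liver at 471 probe sets, 226 with a higher and 245 with a lower effect in microdissected liver, and 10.8% of them were above the floor on every array compared. Probe set af096291_at had an 8.26-fold higher CA effect in microdissected liver (log2 3.05 ± 0.78, SE, adjusted p = 0.0135). Its intensity was 51 and 109 on the CA arrays against 7.5 ± 2.12 (SD, n = 2) in microdissected controls, and 41.1 ± 13.5 (SD, n = 8) and 49.2 ± 37.8 (SD, n = 6) against 31.9 ± 13.6 (SD, n = 8) in entire sections. The limits given above for CA in microdissected liver, a pooled spread and a GAPDH ratio that moved with CA, hold for this comparison too. The effect on aj131902_g_at was 6.87-fold higher (log2 2.78 ± 0.67, SE, adjusted p = 0.00746), but both microdissected controls had an intensity of 6, just above the floor, and with a floor of 20 it was 2.78-fold (adjusted p = 0.0788). Probe set af096291_at was 4.61-fold with that floor (adjusted p = 0.0373). Probe set aj006340_s_at had a 5.60-fold lower effect (log2 -2.49 ± 0.51, SE, adjusted p = 0.00127) and rc_aa893406_at a 5.53-fold lower one (log2 -2.47 ± 0.66, SE, adjusted p = 0.0183). Each of these 4 calls was lost under another setting: array weights ended af096291_at, aj131902_g_at and rc_aa893406_at (adjusted p = 0.0817, 0.0930 and 0.108), and the deposited scale ended aj006340_s_at (adjusted p = 0.0750). Leaving out microdissected control replicate 2 ended af096291_at (adjusted p = 0.0716) and leaving out replicate 1 ended rc_aa893406_at (adjusted p = 0.0983). The count was 770 without microdissected control replicate 1, 50 on the deposited scale, 85 above the 75th percentile, 228 with array weights and 1052 when only microdissected and entire groups gave the spread.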

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

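The tests of RNA integrity, of smaller CA effects and of the stained arrays with a high 5S rRNA signal were chosen after the result was seen, as were the intervals of the shares of splits. The tests of the 5' side of transcripts, of the spread between arrays and of other splits of the arrays were chosen before. Arrays that stood apart from the others of their group were sought in 111 sets of values and found in 23, where chance gives about 1 in 20, or 5.55.

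Stained and entire control sections differed at 2475 probe sets, and no biological difference between the preparations was tested. Chance can be excluded, since the real split gave 2475 calls and the highest of the other splits drawn gave 1376, with 1 of 100 splits as large. Loss of RNA integrity and loss of the 5' side of transcripts remain open as technical explanations. The staining difference correlated across probe sets at 0.435 with the slope on the GAPDH 3'/5' ratio among the 14 entire-section CA arrays, which are other arrays than the controls compared. That slope rests largely on replicate 7 at 0.29% CA and replicate 5 at 0.54% CA, with ratios of 5.07 and 6.49. The other arrays of those doses reached at most 2.65 and 2.37. Among probe sets with a mean intensity above 66, the log2 difference of stained from entire controls had a median of 0.34 for IDs that start with rc_. For those with cds in the ID it was -1.04. These medians lay 1.38 apart (95% bootstrap interval over probe sets 0.98 to 1.55, 951 and 169 probe sets). Part of the difference may thus come from loss of the 5' side, if the former are expressed sequence tags and the latter coding sequence, as was assumed from the IDs.

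Fewer CA effects were called in stained than in entire sections, 499 against 1236 at 0.54% and 286 against 877 at 0.29%, an order that turned with all 15 groups in the fit (964 against 790 and 546 against 539), where the spread is pooled. When noise was added to the entire-section arrays up to the spread of stained arrays, with array numbers matched, they gave a median of 531 calls at 0.54% (470 to 618 in 21 draws) and 367 at 0.29% (335 to 453), so the larger spread could account for most of the gap. Probe sets with a smaller spread in stained sections kept their entire-section spread. The simulated spread may therefore exceed the stained one, which would lower these counts. At 0.29%, effects shrunk evenly to 91.3% with array numbers matched still gave a median of 601 calls (569 to 730), so shrinkage of that size is not the whole cause. The 91.3% was measured on 233 and 205 probe sets called and at least 2-fold in 1 part of the entire-section arrays. Over all entire-section calls tested in both preparations, the slope of stained on entire effects was 0.773. Those calls were made on the same entire-section arrays that gave the effects, which by itself tends to lower this slope. Stronger or uneven shrinkage was not tried, so smaller effects are not excluded. At 0.54% shrinking to 87.4% gave a median of 804 (710 to 951), which exceeds 499 by over 1.5 times in the median but not in every draw, so a part played by smaller effects stays open. A biological difference in the CA effect between the sections was tested only by the test of the difference, which called 7 and 11 probe sets.

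Of the stained arrays, 3 had a 5S rRNA intensity above 200: control replicate 8 at 232 and replicate 7 at 0.29% CA at 241, where the others lay at 19 to 75 and 15 to 50, and replicate 5 at 0.54% CA at 229, which stood apart less clearly from the others at 14 to 129. A wrong label between control and CA is excluded, since 0 of the 3 had a CA score on the side of the other treatment arm (-1.58, 1.12 and 2.04 against a midpoint of -0.08). A wrong label between the CA doses is excluded too, since 0 of the CA arrays lay on the other dose's side, and the other stained arrays scored 1.06 to 1.35 at 0.29% and 1.65 to 1.74 at 0.54%. Their deviations from the other stained arrays of their dose correlated with those of the LCM-reference-time sections at a median of 0.577, against a median of 0.087 and a maximum of 0.412 for the other 17 stained arrays. Handling shared with the LCM-reference-time sections is a candidate explanation that stays open, and no biological explanation was tested.

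Stained replicate 7 at 0.29% CA also had 1482 probe sets above an intensity of 66, and its 50 brightest probe sets took 34.3% of the signal, while stained replicate 5 at 0.54% had a CA score of 2.04 beside 1.65 to 1.74 for the others.

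The fitted difference in the CA effect between stained and entire sections passed the test for rc_aa799326_s_at (-3.46 at 0.29% and -5.38 at 0.54%) and ab005743_g_at (-3.19 and -4.59). Both were at the floor on every stained array, controls included, so the values restate the rise in entire sections. Whether the rise was absent after staining or the signal was not detected was not tested. Those tests called 7 probe sets at 0.29%, where 6 of 100 splits gave as many and the highest other gave 284. They called 11 at 0.54%, where 4 of 100 splits gave as many and the highest other gave 151. The 95% interval for the share of other splits reached 8.60% at 0.54%. These splits mixed control with CA arrays within each preparation and can carry the CA effect itself into the difference. They therefore cannot decide whether chance gave the calls, and chance is not excluded at either dose. For the same reason, the splits with 284 and 151 calls, many more than the real ones, do not by themselves point to another structure among the arrays. The effect differed between microdissected and entire liver at 471 probe sets.

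No splits were drawn for the 3 microdissected comparisons. For CA against control in entire and in stained sections chance can be excluded by the splits drawn. Between the doses it is not firmly excluded for the number of calls. The 95% interval for the share of other splits with as many calls reached 5.50% in entire and 8.60% in stained sections, past the limit of 5%. The CA score, on other probe sets than these calls, did part the doses in stained sections, which had no part in its choice. It was 1.06 to 1.35 at 0.29% and 1.65 to 2.04 at 0.54%, which argues against chance for a dose difference in that score. In entire sections the real counts of 877, 1236 and 79 for 0.29% against control, 0.54% against control and 0.54% against 0.29% stood beside highest other counts of 267, 387 and 495, with 1, 1 and 2 of 100 splits as large. In stained sections 286, 499 and 5 stood beside 64, 94 and 23, with 1, 1 and 4 of 100 as large. The dose split with 495 calls parted arrays by their GAPDH ratio, with a difference of -0.88 in its log2 against 0.47 for the real split, and the stained split with 23 calls had a difference of -1.30, the largest drawn. The splits with 267 and 387 calls had differences of only 0.12 and -0.12. The 495 calls, several times the real 79, point to a structure among the arrays whose source was not tested.

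Among entire sections, 3 arrays stood apart in the GAPDH and beta-actin 3'/5' ratios. Control replicate 7 had ratios of 6.25 and 6.43, replicate 7 at 0.29% CA 5.07 and 5.15, and replicate 5 at 0.54% CA 6.49 and 7.66. Control replicate 7 also had a 3' GAPDH log2 intensity of 10.08, a 3' beta-actin log2 intensity of 8.98, and log2 intensities of 7.11 for rc_aa893406_at and 7.28 for x15734_at. Replicate 6 at 0.29% CA had a 3' beta-actin log2 intensity of 8.12.

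The 50 brightest probe sets of entire replicate 6 at 0.54% CA took 24.2% of the signal, and its log2 intensities were 6.98 for af096291_at, 6.21 for aj131902_g_at and 12.28 for j02749_at. Other single values that stood apart were log2 9.17 for j00738_s_at in entire replicate 8 at 0.29% CA, 10.54 for k03249_at in stained replicate 4 at 0.54% CA, and 8.44 for m93297cds_at in entire control replicate 4.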

How the results depend on the processing

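The alternatives chosen after seeing the data were quantile normalization before the floor, the filter at the 75th percentile, the GAPDH covariate and the fits without the arrays in doubt. Of 144 alternative counts of called probe sets, 98 lay within 1.5 times the reported count and 46 did not. The 24 alternative correlations between preparations differed from the reported ones by less than the spread of single stained pairs. For the probe sets named by ID, 532 of 557 alternative values kept direction and call, 25 kept the direction and lost the call, and 0 reversed. Of the fits without 1 array, only those with the lowest and highest log2 fold change of each probe set entered this tally. Most of the losses of m15114_g_at and j02657_s_at in such fits are therefore not in it. Except where stated, the cause was not tested. The alternatives for gene lists were not run, since no probe set has a gene name.

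With all 15 groups in the fit, entire sections gave 539 calls at 0.29%, 790 at 0.54% and 41 between doses, and stained sections 546, 964 and 18. There the spread of both preparations is pooled, which raises it for entire sections and lowers it for stained ones. With the spread taken from microdissected and entire groups alone, CA in microdissected liver gave 1841 calls and its difference from entire liver 1052. A 2-fold minimum, which removes smaller changes by its construction, left 356, 558 and 32 calls in entire sections and 1444 for stained against entire controls.

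The cause was not tested for the following. Array weights gave 1933 calls at 0.54% and 331 between doses in entire sections, 19 between doses in stained sections, 15 and 22 for the differences between stained and entire sections at 0.29% and 0.54%, and 335, 328 and 228 for the 3 microdissected comparisons. The deposited scale gave 34 between doses in entire and 1 in stained sections, 3798 for stained against entire controls, 312 for CA in microdissected liver and 50 for its difference from entire liver. On that scale the median of all probe sets also shifted by -0.13 for the difference between stained and entire sections at 0.54%. A floor of 20 gave 132 and 10 between doses in entire and stained sections and 16 and 30 for the differences between them. The replicate block gave 211 and 1 between doses in entire and stained sections. In stained sections it ended the calls of m15114_g_at (adjusted p = 0.0861) and j02657_s_at (adjusted p = 0.127). The replicate numbers were not shown to pair arrays: of 57 pairs of equal number between 9 pairs of groups, 32 correlated above 0.1 and 15 were the best match, with correlations from -0.49 to 0.78. Between doses in stained sections, the prior with trend and robust fitting gave 10 calls, and quantile normalization before the floor gave 8.

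The filter at the 75th percentile, by which fewer probe sets were tested, gave 8 calls between doses in stained sections, 1582 for stained against entire controls, and 509, 1312 and 85 for the microdissected comparisons. The GAPDH covariate gave 301 for 0.54% CA and 2 between doses in stained sections, 400 for stained against entire controls, 6 for the difference at 0.54% and 897 for microdissected against entire controls. The ratio differed between stained and entire controls, so in that comparison the covariate and the preparation overlap. For the other counts the cause was not tested. Without the arrays in doubt there were 3 calls between doses in stained sections and 17 and 22 for the differences between stained and entire sections.

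Leaving out 1 array at a time gave 194 fits, of which 27 moved a count by over 1.5 times. In entire sections the counts ranged from 761 to 934 at 0.29%, 1052 to 1380 at 0.54% and 33 to 118 between doses. In stained sections they ranged from 240 to 292, 362 to 531 and 1 to 9. They ranged from 2219 to 2588 for stained against entire controls, and from 6 to 13 and 7 to 20 for the differences at 0.29% and 0.54%. For microdissected liver they ranged from 698 (without control replicate 2) to 1142 for CA, 923 (without control replicate 2) to 2163 against entire controls, and 350 to 770 (without control replicate 1) for the difference. Signal over background was low in part of the calls: 33.9% of those for CA in microdissected liver were above the floor on every array compared, 10.8% of those for its difference from entire liver, and 0% of those for the differences between stained and entire sections, against 80.2% at 0.29% CA in entire sections.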

Other observations

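The values in this part were computed after the data had been examined. The median spike-in and ribosomal signals were higher on LCM-reference-time and microdissected arrays than in the other preparations, with overlapping ranges. The 3' Cre control, a spike-in transcript, had a median intensity of 4722 in entire sections, 7906 in stained and 5096 in dehydrated sections, 25121 in LCM-reference-time sections and 20602 in microdissected liver. Stained arrays reached 21367 and a microdissected array had 9746. The 5S rRNA control had medians of 44.5, 40, 17, 152 and 302 in the same order, with stained arrays up to 241 and a microdissected array at 97.

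The number of probe sets called against the GAPDH 3'/5' ratio, with dose in the model, was 984 in entire sections (476 higher and 508 lower with a higher ratio) and 30 in stained sections (0 higher and 30 lower). Of 87 accessions with more than 1 probe set called at 0.54% CA in entire sections, 85 had all of them changed in the same direction.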
